A study of Homo sapiens with 36 samples.

How the data were processed

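The data are 36 peak lists and 2 tables from A549 cells treated with SAHA or vehicle for 24 or 48 h, with 3 libraries in each of 12 groups. Groups and replicate numbers come from the sample labels, which call the replicates biological and give no sequencing batch. Per the submitters' processing notes the tools were BWA, SAMtools, MACS2 and DESeq2, with the T2T-CHM13 assembly; versions and parameters are not given in the sources used here. Each library has its own list, so replicates were not pooled for peak calling. Each line of a list is a summit, and several summits can share an interval, so distinct intervals were counted as peaks. The deposited fold enrichment (a ratio), −log10 p, −log10 q and score of each summit are the authors' and were used only to describe, rank or filter peaks within a list. All summits have q of at most 0.05. The authors' deposited tables give the base mean (normalised signal), the log2 fold change with its SE, and the p-value and adjusted p-value of each of 35718 regions. They hold no values per library, so no block, left-out library or other split could be applied to them.

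The regions of both tables are the same, and 100% of their starts and ends equal an interval start or end of the 12 H3K4me3 lists, with 0 regions overlapping another. A positive log2 fold change means higher after SAHA: of the regions with a gained H3K4me3 peak at 24 h (1804), 100% had a positive value in the authors' deposited table, and of those with a lost one (154), 0.649%. The design fixed before the data were examined used promoters of protein-coding genes. The gene table at hand is of the GRCh38.p14 assembly and its positions were not used, so the authors' H3K4me3 regions took the place of promoters, and gene lists, named genes and windows around transcription start sites were not run. The share of peaks at promoters became the share of intervals overlapping an H3K4me3 region by 1 bp or more. It is 100% for H3K4me3 by construction and was not tested there.

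Interval number and covered length (log2) and the share in H3K4me3 regions (percentage points) were compared by an exact two-sided permutation test that exchanged treatment within each time (400 arrangements, smallest p 0.005), with Benjamini-Hochberg adjustment over 8 tests. Folds are those of geometric means. A region gained a peak at a time when all 3 SAHA libraries and no control had one, and lost it in the opposite case. A mark called gained or lost means such a peak, and not the amount of the mark. Over both times, Fisher's exact test (two-sided) compared 6 with 6 libraries, adjusted over regions detected in 5 to 7 of the 12, the totals that can reach a p under 0.05. Peak number measures detection, which depends on depth and enrichment. Differences of median log2 fold change were tested by permuting regions (100000 resamples, 10000 for alternatives). H3K4me3 regions were named where the authors' adjusted p was under 0.05 at both times with the same sign and base mean was at least 50, taking the 12 largest mean rises and falls. For acetylation up to 10 gained and 10 lost regions were ranked by the difference in libraries with a peak and then by the percentile of the peak fold within a list. Windows of 500 bp counted as covered when at least 50% of their length was.

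Sequencing depth is not given. For a summit the fold and p together fix the pileup and the background, and whole pileups (within 0.002 of −log10 p) came out for nearly all of up to 4000 summits tried per library in 35 libraries. In the H3ac library of 24 h SAHA replicate 3 only 2.95% were whole, so its background and strong intervals are not given. Intervals with a summit pileup of at least 20 times the lowest background of the library were called strong. Per the labels' protocols, treated and mock-treated flasks of a biological replicate were processed in parallel, so replicate numbers pair the libraries. Over regions, the deviations of same-numbered control and SAHA libraries from their group means correlated between -0.029 and 0.042 in 18 pairs, and 0 pairs exceeded 0.1. No 2 lists were the same: the largest overlap within a group was 0.859 of the joint covered length. SAHA lists of the acetylation marks overlapped less, at 0.231 to 0.363 for H3ac and 0.222 to 0.322 for H3K27ac. Their control lists overlapped at 0.575 to 0.689 and 0.637 to 0.691. A gained peak needs all 3 SAHA lists and a lost one all 3 control lists, so the 2 counts may differ in sensitivity.

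The procedures were tested on simulated data. With detection drawn from the real controls over 35718 regions, a change in 5000 regions was called in 85.2% of them for H3ac, 83.7% for H3K27ac and 83.4% for H3K4me3. False calls numbered 24, 14 and 17 there, and libraries of unequal depth were not simulated. A change in 200 regions alone gave 0, 92 and 96 calls, so a rare change of H3ac standing alone would be missed over both times. In the data, gained H3ac regions were adjusted together with 4428 lost ones. There every region with an unadjusted p under 0.05 in Fisher's exact test was called, so this limit does not explain the count of gains. Alternatives were a stricter peak threshold (q of at most 0.001), lists of equal length, an overlap of 200 bp, the replicate block, each library left out, stricter thresholds on the tables, and others chosen after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.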

Results

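Chromatin immunoprecipitation and sequencing (ChIP-seq) was carried out on A549 cells, a human lung carcinoma line, treated with 10 µM suberoylanilide hydroxamic acid (SAHA, vorinostat), an inhibitor of histone deacetylases, or with its DMSO vehicle as control. Chromatin taken at 24 and 48 h was precipitated with antibodies to acetylated histone H3 (H3ac), to H3 acetylated at lysine 27 (H3K27ac, found at active promoters and enhancers) and to H3 trimethylated at lysine 4 (H3K4me3, found mainly at promoters). Each of the 12 groups of mark, time and treatment held 3 biological replicates, which gave 36 libraries with a peak list each. For H3K4me3 the authors' deposited table at each time also gave differences between SAHA and control over 35718 regions, called H3K4me3 regions here. The number of reads per library is unknown, and the background recovered from the peak lists, which rises with depth, lay between 0.563 and 2.66 reads in the 35 libraries in which it could be recovered. The design asks how the inhibitor changed the 3 marks and whether the changes differed between 24 and 48 h. Positions are on the T2T-CHM13 assembly, and genes are not named because no gene annotation of that assembly was used here.

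H3ac peaks were fewer, narrower and weaker in SAHA-treated cells. At 24 h the lists held 27342 ± 5057 intervals after SAHA and 44922 ± 8532 in control cells (SD, n = 3 each), and at 48 h 20042 ± 12116 and 40089 ± 4421. The intervals covered 12.1 ± 1.17 Mb after SAHA and 36.0 ± 8.49 Mb in control cells at 24 h, and 8.81 ± 4.78 and 29.1 ± 3.14 Mb at 48 h. Over both times the number of intervals was 0.514 times and the covered length 0.304 times that of the controls, and in both measures all 6 SAHA libraries lay below the controls of their time. The exact two-sided permutation test within times gave p = 0.005 for each, the smallest value it allows, and 0.008 after adjustment over 8 tests. The median interval width was 0.686 times that of controls (exact permutation p = 0.005), and intervals with a summit of at least 20 times the background were 0.121 times as many (exact permutation p = 0.005, with 2 SAHA libraries at 24 h). At each time alone, 3 libraries against 3 cannot reach a p below 0.1. The share of H3ac intervals inside H3K4me3 regions did not pass the test (difference 0.481 percentage points, exact permutation p = 0.905), but differed by -12.5 points in lists of equal length and by 5.52 points among the strong intervals.

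**Figure D1:**
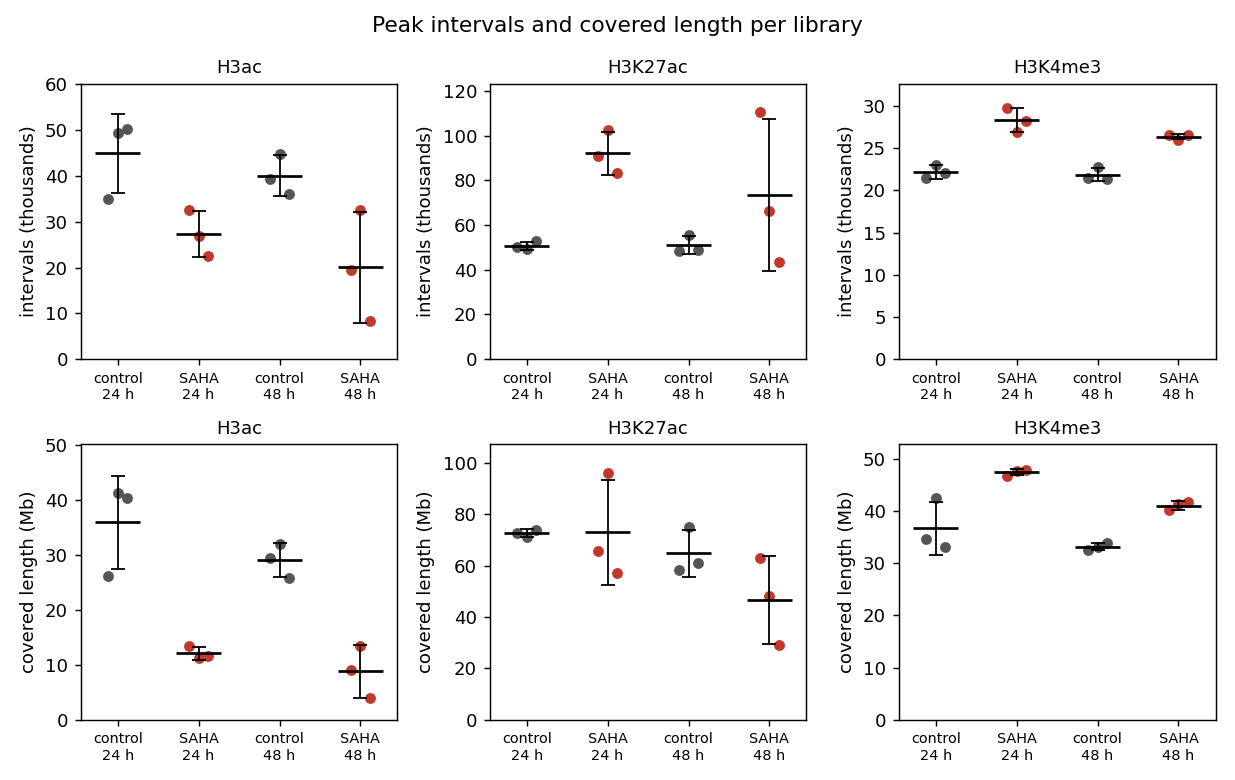
Number of distinct peak intervals (in units of 1000) and the length they cover (Mb) for each mark, time and treatment; points are libraries and bars the mean and SD of 3. All SAHA libraries lie below the controls of their time for H3ac and above them for H3K4me3.

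Many H3K4me3 regions lost their H3ac peak and few gained one. The H3ac lists of SAHA libraries overlapped less with each other than those of controls, and a gain needs all 3 of them. Of 18567 regions with an H3ac peak in all 3 controls at 24 h, 3942 (21.2%) had none in any SAHA library and 7499 (40.4%) had it in all 3. At 48 h these were 3967 (22.7%) and 5280 (30.2%) of 17488. A peak was gained by 15 regions at 24 h and by 2 at 48 h, on chromosome 20 from 49191784 to 49192033 and on chromosome 7 from 151972489 to 151974019, named here after their values were seen. Neither was free of the peak in control cells at 24 h. At that time the region on chromosome 20 had it in 3 control and 2 SAHA libraries, and that on chromosome 7 in 2 and 2. Over both times 4428 regions lost an H3ac peak and 0 gained one (Fisher's exact test of 6 against 6 libraries, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 in that test 0 gained one as well. With the replicate pairs as a block, which calls only regions that changed in all 6 pairs, 1726 lost a peak and 0 gained one. Regions that lost the peak at 24 h had a median width of 1247 bp and those that kept it 3351 bp. The lost regions ranked highest were chromosome 9 from 80284334 to 80285189, chromosome 19 from 57238440 to 57243449 and chromosome 10 from 74643254 to 74646385, each with a peak in 6 of 6 control and 0 of 6 SAHA libraries. In lists of equal length (8280 intervals) 933 regions lost and 174 gained a peak over both times. At 24 h 1200 lost and 266 gained one in these lists, and at 48 h 825 and 249. Without the SAHA libraries of replicate 3 (no recoverable background at 24 h, the lowest background at 48 h) 1957 lost a peak over both times. With fewer libraries, which loosens the rule, the gained count without control replicate 2 or SAHA replicate 1, 2 or 3 was 29, 44, 43 or 49 at 24 h and 4, 6, 4 or 50 at 48 h, without SAHA replicate 3 of 48 h it was 11 over both times, and without SAHA replicate 2 the lost count at 48 h was 7199.

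A smaller share of H3K27ac intervals lay in H3K4me3 regions after SAHA. At 24 h it was 20.3 ± 1.28% after SAHA and 42.1 ± 1.05% in control cells (SD, n = 3 each), and at 48 h 26.9 ± 8.49% and 43.8 ± 3.43%. The difference over both times was -19.3 percentage points (exact two-sided permutation p = 0.005, adjusted 0.008), and all 6 SAHA libraries lay below the controls of their time. Among strong intervals the difference was -7.59 points (exact permutation p = 0.015, with the replicate pairs as a block 0.0625), with -1.77 at 24 h and -13.4 at 48 h. Outside these regions the lists held 73507 ± 8794 intervals after SAHA and 29388 ± 1558 in control cells at 24 h, and 55590 ± 31850 and 28683 ± 4079 at 48 h, 2.08 times the control number over both times (exact permutation p = 0.01). Inside them the number was 0.835 times that of controls (exact permutation p = 0.005). The H3K27ac length inside H3K4me3 regions was 13.8 ± 2.48 Mb after SAHA and 32.0 ± 0.187 Mb in control cells at 24 h, and 12.1 ± 1.80 and 30.6 ± 1.68 Mb at 48 h, 0.41 times the control length over both times (exact permutation p = 0.005). Outside them the length was 59.2 ± 17.9 and 40.6 ± 1.30 Mb at 24 h and 34.7 ± 16.1 and 34.3 ± 7.42 Mb at 48 h, which did not pass the test (exact permutation p = 0.445). The number of intervals was 1.56 times that of controls (exact permutation p = 0.02, adjusted 0.0267), but with the replicate pairs as a block exact p = 0.0625, at the stricter peak threshold the log2 difference was 0.030, and it was -0.23 for summits and -3.77 for strong intervals. The covered length did not pass the test (0.823 times, exact permutation p = 0.24), but did without the SAHA library of replicate 2 at 24 h (log2 -0.39, exact permutation p = 0.02) and at the stricter peak threshold (log2 -0.73, exact permutation p = 0.01).

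**Figure D2:**
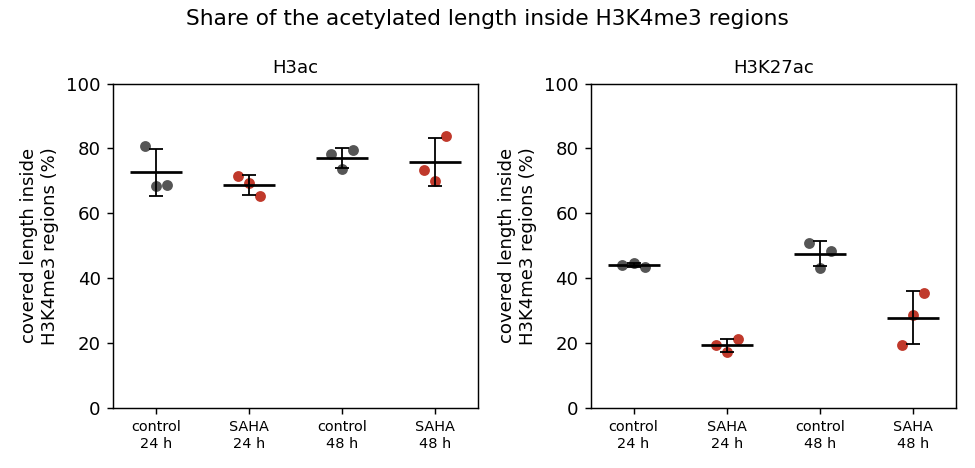
Share of the length covered by H3ac and H3K27ac intervals that lies inside H3K4me3 regions (%), by time and treatment; points are libraries and bars the mean and SD of 3. For H3K27ac the SAHA libraries lie between 17.3% and 35.4% and the controls between 43.2% and 50.8%.

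Within H3K4me3 regions, far more H3K27ac peaks were lost than gained, and more were kept than lost. Here too the SAHA lists overlapped less with each other than the control lists, and a gain needs all 3 of them. At 24 h 4654 of 19955 regions with a peak in all 3 controls (23.3%) had it in no SAHA library, 8912 (44.7%) had it in all 3, and 202 regions gained it. At 48 h 3805 of 19361 (19.7%) lost it, 9690 (50.0%) kept it and 41 gained it. Among regions with an H3K4me3 peak in all 6 controls only 1 gained it at 24 h, 1 at 48 h and 0 over both times. In that set 3398, 2927 and 3459 lost it. Over both times 4516 regions lost and 49 gained a peak (Fisher's exact test of 6 against 6 libraries, adjusted p under 0.05), and with the replicate pairs as a block 2284 and 9. Peaks of both acetylation marks were lost at 24 h by 1445 regions, where independent sets would share 689. Lost regions of either mark were narrower than kept ones (median 1247 against 3351 bp for H3ac and 1604 against 3062 bp for H3K27ac). The expectation does not allow for this, and whether it accounts for the excess was not tested. The lost regions ranked highest included chromosome 1 from 16125867 to 16126901 and chromosome 19 from 13959191 to 13959806, with a peak in 6 of 6 control and 0 of 6 SAHA libraries. The gained ones included chromosome 16 from 81616878 to 81617066 and chromosome 20 from 3795441 to 3795912, with the opposite pattern. In windows of 500 bp, 9.20 Mb outside H3K4me3 regions gained H3K27ac at 24 h and 1.03 Mb at 48 h, and 9.69 and 5.10 Mb lost it. In lists of equal length (43552 intervals) 7071 regions lost and 126 gained a peak at 24 h, and over both times 28 gained it. With a SAHA library left out, which loosens the rule, the gained count was 340 without replicate 1 and 356 without replicate 3 at 24 h, 62, 68 and 107 without replicates 1, 2 and 3 at 48 h, and over both times 91 and 113 without replicates 2 and 3 of 48 h.

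H3K4me3 peaks were more numerous after SAHA. The lists held 28326 ± 1426 intervals after SAHA and 22197 ± 823 in control cells at 24 h (SD, n = 3 each), and 26396 ± 339 and 21879 ± 794 at 48 h. Over both times this was 1.24 times the control number and 1.27 times the covered length, and in both measures all 6 SAHA libraries lay above the controls of their time (exact two-sided permutation p = 0.005 for each, adjusted 0.008). Strong intervals were 1.06 times and summits 1.48 times as many as in controls (exact permutation p = 0.005 for each). A peak was gained by 1804 and lost by 154 regions at 24 h, and gained by 1254 and lost by 72 at 48 h. Over both times 1067 regions gained and 83 lost a peak (Fisher's exact test of 6 against 6 libraries, adjusted p under 0.05), and 413 and 28 with the replicate pairs as a block. In lists of equal length (21366 intervals) 575 regions gained and 401 lost a peak at 24 h, 366 and 221 at 48 h, and 288 and 239 over both times. With fewer libraries, which again loosens the rule, the lost count was 263 and 316 without control replicates 1 and 3 at 24 h, 145 and 135 without control replicates 1 and 3 and 109 without SAHA replicate 3 at 48 h, and 129 over both times without control replicate 1 of 48 h.

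H3K4me3 was higher at weak, narrow regions and slightly lower at strong, broad ones. At 24 h the authors' deposited table held 12026 higher and 10796 lower regions after SAHA at an adjusted p under 0.05 (DESeq2), with median log2 fold changes of 1.44 and -0.45 and median widths of 609 and 2797 bp. At 48 h the authors' deposited table held 8051 higher and 8296 lower regions, with medians of 1.18 and -0.31. In the 20% of regions with the lowest base mean the median log2 fold change in the authors' deposited table was 1.41 at 24 h and 0.88 at 48 h, and in the 20% with the highest it was -0.33 and -0.19. Of these strongest regions 78.5% were lower at 24 h and 63.5% at 48 h in the authors' deposited table. The median H3K4me3 summit fold of the lists was also lower after SAHA, at 13.8 against 23.3 in controls at 24 h and 16.3 against 22.0 at 48 h. These medians cover unlike sets, since SAHA lists held 1.48 times as many summits, and strong intervals were 1.06 times as many. A lower ratio of signal to background could move weak regions up and strong ones down, and was not excluded. Weak regions may also be listed because SAHA libraries called them, which was not tested for weak against strong regions. The authors' deposited tables shared 5959 higher regions, where independent lists would share 2711, and 7126 lower regions, where they would share 2508. Their log2 fold changes at 24 and 48 h correlated across the 20209 regions with a base mean of at least 50 (Pearson's r = 0.79, Spearman's rho = 0.76; regions are not independent replicates). At that base mean 4788 regions were higher and 10114 lower at 24 h, and 3846 and 7828 at 48 h, in the authors' deposited tables. Among regions with a peak in all 12 libraries 3248 were higher and 9788 lower at 24 h, and 2508 and 7575 at 48 h, in the authors' deposited tables. With a log2 fold change of at least 1 in size the authors' deposited tables held 8269 higher and 883 lower regions at 24 h, and 4735 and 578 at 48 h.

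Single regions changed far more than these medians. The rule fixed for naming regions was passed by 2990 rising and 6872 falling regions in the authors' deposited table. The 12 largest rises had mean log2 fold changes over both times between 3.67 and 4.95. They were led in the authors' deposited table by chromosome 4 from 77782443 to 77784100 (5.21 ± 0.38 at 24 h and 4.68 ± 0.63 at 48 h, authors' SE), chromosome 12 from 6727326 to 6730901 (5.92 ± 0.18 and 3.37 ± 0.23) and chromosome 1 from 153808690 to 153814318 (6.33 ± 0.21 and 2.51 ± 0.23). None of the 12 had an H3ac or H3K27ac peak in any control library, and 10 had no H3K27ac peak in any SAHA library either. The 12 largest falls had means between -3.77 and -2.42, led in the authors' deposited table by chromosome 11 from 1229096 to 1236043 (-4.20 ± 0.19 and -3.34 ± 0.18), chromosome 6 from 34376897 to 34380503 (-3.55 ± 0.14 and -3.36 ± 0.13) and chromosome 16 from 63400607 to 63402285 (-3.86 ± 0.34 and -2.98 ± 0.29). Of these 12, 9 had an H3K27ac peak in all 6 control libraries and 3 in all 6 SAHA libraries.

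The H3K4me3 change differed with the acetylation of a region in control cells. The 15758 regions with both acetylation marks in all 6 controls had a median log2 fold change of -0.26 at 24 h and -0.14 at 48 h in the authors' deposited table, and 58.8% and 44.6% of them were lower. The 9520 regions with neither mark in any control had medians of 1.37 and 0.93 in the authors' deposited table, and 61.9% and 39.5% were higher. The unacetylated regions were also far weaker, with a median base mean of 16.0 against 1202. At matched read density (base mean per bp) the difference of medians at 24 h was 0.60, against 1.63 unmatched, over 9499 unacetylated and 4701 acetylated regions. This density averages SAHA and control libraries and so contains the change. Among regions with an H3K4me3 peak in all 12 libraries the medians in the authors' deposited table were -0.31 and -0.18 for 12726 acetylated regions and 0.66 and 0.42 for 675 without acetylation. The median base means of these were 1513 and 141.6. These classes were chosen after the data were examined.

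**Figure D3:**
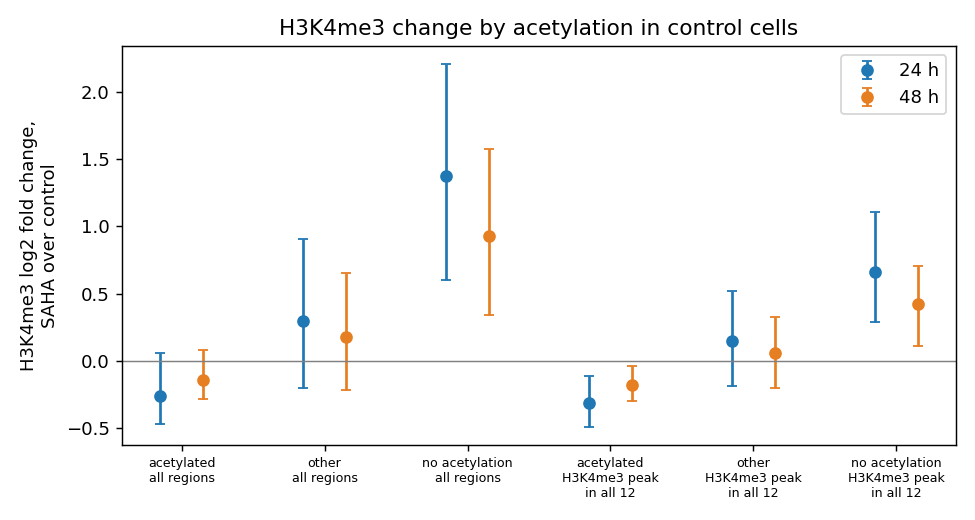
H3K4me3 log2 fold change, SAHA over control, from the authors' deposited table, by acetylation of the region in control libraries, for all regions and for those with a peak in all 12 libraries; points are medians and bars the middle 50% of regions, and regions in neither class are shown as other. Medians are below 0 for acetylated regions and above 0 for regions without acetylation.

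The H3K4me3 change of regions that lost an acetylation peak was compared with that of regions that kept it. In the authors' deposited table the median log2 fold change at 24 h was -0.15 in the 3942 regions that lost H3ac and -0.26 in the 7499 that kept it, and at 48 h -0.06 and -0.17. Of the regions that lost H3ac 37.8% were lower at 24 h and 28.2% at 48 h in the authors' deposited table, and of those that kept it 64.3% and 55.7%. Median base mean at 24 h was 190.3 in lost and 1929 in kept regions in the authors' deposited table. For H3K27ac the medians in the authors' deposited table were -0.26 in lost and -0.19 in kept regions at 24 h, and -0.17 and -0.10 at 48 h. Each difference had p = 1e-05 in a two-sided permutation test over regions, the smallest it can give, which describes regions and is no replicate test. Among regions matched on base mean the H3ac difference (lost minus kept) turned from 0.11 at each time to -0.49 at 24 h and -0.27 at 48 h, and in lists of equal length it was -0.10 and 0.00. Without H3ac control replicate 1 the unmatched difference was 0.19 at 24 h. For H3K27ac the matched difference was -0.34 and -0.28, in the direction of the unmatched one. Base mean averages SAHA and control libraries and so contains the change itself, and matching on it cannot decide how lost and kept regions differ. The H3ac matching used 5862 of 7499 kept regions at 24 h and 3880 of 5280 at 48 h.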

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

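The tests of the shallowest library, of the number of H3K27ac intervals outside H3K4me3 regions, of the slopes on background, of antibody enrichment, of listed regions and of both scaling explanations were chosen after the result was seen, and the measure of strong intervals was added after the data were examined. Effects that differed between 24 and 48 h came from 35 tests of that difference on the peak lists, of which 3 had an exact permutation p under 0.05 where chance gives 1.75, and the smallest adjusted p was 0.175. The log2 effect on strong H3K27ac intervals was 2.84 higher at 48 h than at 24 h (exact permutation p = 0.01). The effect on the share of strong H3K27ac intervals in H3K4me3 regions was -1.77 percentage points at 24 h and -13.4 at 48 h, a difference of -11.6 (exact permutation p = 0.01). The log2 effect on H3K4me3 summits differed by -0.37 (exact permutation p = 0.02). The H3K4me3 change differed between the times in 6423 regions of the authors' deposited tables (Wald test taking the times as independent, adjusted p under 0.05), and 4300 of these had a smaller change of the same sign at 48 h.

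H3ac intervals were fewer after SAHA, although the drug inhibits deacetylation. Lower depth is argued against by the strong intervals, which every depth here detects, with a log2 ratio of -3.05, and the recovered background was 1.07 times that of controls (exact permutation p = 0.74). Without the shallowest library, SAHA replicate 3 of 48 h, the log2 ratio of all intervals was -0.69 (exact permutation p = 0.005). Weaker enrichment by the antibody cannot be told apart from acetylation spread so widely that peaks stand out less: the log2 ratio outside minus inside H3K4me3 regions was -0.053, short of either bound set for it, and no reference added to the chromatin was analysed here. Both may apply.

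Weak peaks near the threshold cannot be excluded as a reason for the lower share of H3K27ac intervals in H3K4me3 regions. Lists of equal length gave -18.0 percentage points, but they match the rank of peaks and not their strength. Among strong intervals the difference was -1.77 points at 24 h and -13.4 at 48 h. At 24 h the SAHA lists held a mean of 333 strong intervals and the control lists 12095. Splitting of intervals is argued against by the share of covered length, at -22.3 points. Lower depth is argued against as the reason for more intervals outside, since a shallower list holds fewer, and after SAHA they were 2.08 times as many (log2 1.06, exact permutation p = 0.01). How far depth adds to the lower share cannot be told apart: the first test of it, on strong intervals, gave -7.59 points (exact permutation p = 0.015, with the replicate block 0.0625), between its bounds, at a background 0.74 times that of controls (exact permutation p = 0.02, with the block 0.0625). Of 4 slopes on background within groups (share and outside number, H3K27ac and H3ac), that of the H3K27ac share was -14.8 points per doubling (exact permutation p = 0.0185, adjusted 0.0278), against depth, but without the 2 libraries farthest in background it was -7.84 (exact permutation p = 0.118), so it rests on these, and a redistribution of H3K27ac by the drug may be proposed as a hypothesis only.

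H3K4me3 rose at regions without acetylation and fell at acetylated ones. Listing of regions because SAHA libraries called them is argued against by a difference of medians of 0.98 at 24 h among regions with a peak in all 12 libraries. That difference is not one of acetylation alone, since regions without it were still weaker there (median base mean 141.6 against 1513). A lower ratio of signal to background cannot be excluded. The median H3K4me3 summit fold was 13.8 after SAHA and 23.3 in controls at 24 h, and 16.3 and 22.0 at 48 h. SAHA lists held 1.48 times as many summits, so these medians cover unlike sets. At matched read density the difference was 0.60 ± 0.03 (bootstrap SE), over 9499 regions without acetylation and 4701 acetylated ones. That density averages SAHA and control libraries and so contains the change itself, and the matching cannot decide the question. Scaling alone is argued against by the difference of 1.63 between the classes. The fall of the acetylated regions itself (-0.26) cannot be told apart from scaling of the libraries, since no reference outside the regions was analysed here. A shift of the mark toward unacetylated regions may be proposed as a hypothesis only.

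Over both times 100 splits of the 12 libraries were counted, the real one included, and 1 of 100 gave as many lost H3ac (4428), lost H3K27ac (4516), gained H3K27ac (49), gained H3K4me3 (1067) or lost H3K4me3 (83) regions as the real split. The highest of the others was 0, however many replicate pairs they parted. The adjustment calls nothing unless many regions reach the smallest p together, so a split that mixes the treatments was likely to give 0. These splits argue against chance for the changes of a mark in both directions together. They cannot decide it for the rarer direction, adjusted together with the commoner one. Of the 49 gained H3K27ac and 83 lost H3K4me3 regions, 9 and 28 differed between all 6 SAHA and all 6 control libraries. For gained H3ac regions 100 of 100 splits gave the real count of 0. At a single time there are 10 splits, too few for a share under 0.05. There the real split, as 1 of 10, gave the highest count for lost H3ac (3942 and 3967 at 24 and 48 h, highest other 225 and 152), lost H3K27ac (4654 and 3805, highest other 33 and 73), gained H3K4me3 (1804 and 1254, highest other 115 and 88), gained H3K27ac at 24 h (202, highest other 33) and lost H3K4me3 at 24 h (154, highest other 115). The real count was reached by 7 of 10 splits for gained H3ac at 24 h (15, highest other 225), 10 of 10 at 48 h (2, highest other 152), 4 of 10 for gained H3K27ac at 48 h (41, highest other 73) and 2 of 10 for lost H3K4me3 at 48 h (72, highest other 88). Each of the other 9 splits mixes the treatments.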

How the results depend on the processing

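The strong intervals, summits, share of covered length, regions extended by 1 kb, regions with H3K4me3 in all 6 controls or all 12 libraries, matching on base mean and the omission of both doubted libraries were chosen after seeing the data. Of the main results' values under alternatives, 319 kept direction and side of the threshold or stayed within 1.5 times, 85 moved, 12 reversed, 3 became stronger and 3 weaker. The named regions were recomputed only after centring on the median, which shifts all of them alike and tests nothing. The direction of the H3ac and H3K4me3 interval numbers and lengths and of the H3K27ac share held in every alternative run. Depth limits all counts, since a shallow list misses weak peaks; the cause of the changes below was not tested, except that fewer libraries or regions, or a stricter rule, change a count by construction.

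For H3K27ac intervals (log2 0.64) the stricter threshold gave 0.030, summits -0.23 and strong summits -3.77, and with the replicate block 0.64 had exact p = 0.0625. The block also gave 1726 lost H3ac, 9 gained and 2284 lost H3K27ac, and 413 gained and 28 lost H3K4me3 regions over both times. Besides that of H3K27ac intervals, the block ended the calls of a lower background of H3K27ac libraries and of a lower share of strong H3K27ac intervals in H3K4me3 regions (exact p = 0.0625 each). It changed no other call across libraries that it was run on, at an unadjusted p under 0.05. Its p-values, at best 0.03125, were not adjusted over the 8 tests. It was not run on the strong H3ac intervals and their share, where a library lacks a background, nor on the differences between times. H3K27ac covered length was -0.73 at the stricter threshold and -0.41 to -0.13 with a library left out. The H3K27ac share was -7.59 points for strong summits, against -19.3. H3K4me3 intervals (log2 0.31) gave 0.56 for summits and 0.083 for strong summits. The H3ac share was -12.5 points at equal list length, -2.68 by covered length, 5.52 for strong summits, -2.60 without both doubted libraries and -2.68 to 3.05 with a library left out, below 0 without control replicates 2 or 3 of 24 h, control replicate 2 of 48 h or SAHA replicate 3 of 48 h.

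Gained H3ac regions at 24 h numbered 6 at the stricter threshold, 266 at equal list length, 9 at an overlap of 200 bp, 36 with regions extended by 1 kb, 4 among regions with H3K4me3 in all 6 controls and 18 to 49 with a library left out. At 48 h they were 249 at equal length, 1 at an overlap of 200 bp, 1 with extended regions, 1 among regions with H3K4me3 in all 6 controls and 2 to 50 with a library left out. Over both times they were 174 at equal length, 1 at an overlap of 200 bp and 0 to 11 with a library left out. Lost H3ac regions at equal length were 1200, 825 and 933 (24 h, 48 h, both times) and among regions with H3K4me3 in all 6 controls 2461, 2575 and 2896; both times without both doubted libraries gave 1957, and 48 h with a library left out 4046 to 7199.

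Gained H3K27ac regions (24 h, 48 h, both times) were 128, 22 and 26 at the stricter threshold, 126, 25 and 28 at equal length, 120, 19 and 24 at an overlap of 200 bp, 308, 66 and 120 with extended regions, and 1, 1 and 0 among regions with H3K4me3 in all 6 controls. With a library left out they were 221 to 356, 47 to 107 and 53 to 113. Lost H3K27ac regions at 24 h were 7071 at equal length. Gained H3K4me3 regions were 575, 366 and 288 at equal length, and 2740 at 24 h with extended regions. Lost ones were 401, 221 and 239 at equal length, 58, 47 and 49 among regions with H3K4me3 in all 6 controls, and 183 to 316, 100 to 145 and 88 to 129 with a library left out.

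In the authors' deposited tables higher regions at base mean of at least 50 were 4788 and 3846 (24 and 48 h) against 10114 and 7828 lower, and with H3K4me3 in all 12 libraries 3248 and 2508 against 9788 and 7575. With a log2 fold change of at least 1 in size, higher regions were 8269 and 4735 and lower ones 883 and 578. The difference between lost and kept H3ac regions in those tables was -0.098 at 24 h and 0.0029 at 48 h at equal length, and -0.49 and -0.27 matched on base mean. Base mean contains the change itself, so the matched values cannot decide the direction.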

Other observations

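The test of chromosome density was chosen after the result was seen, and that of random spread before. H3K27ac windows gained outside H3K4me3 regions were unevenly spread over the chromosomes. At 24 h chromosomes 19 and 17 held 6.69 and 6.59 times the gained windows that their share of windows gives, and chromosomes 16, 12 and 20 held 2.52, 2.15 and 1.98 times. Chromosomes 13, 18 and 4 held 0.0162, 0.0208 and 0.0416 times. At 48 h chromosomes 19 and 17 stood highest too, at 6.95 and 4.87 times. Lost windows ranged at 24 h from 0.543 times on chromosome X to 1.55 times on chromosome 20, and at 48 h from 0.495 times on chromosome X to 1.96 and 2.07 times on chromosomes 17 and 19, which thus stood highest for gains and losses alike at 48 h.

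Windows gained at both times numbered 686, which was 110 times the number that independent draws from all windows outside H3K4me3 regions give. It was 5.14 times that from windows with a peak in any SAHA library. An even random spread is argued against. However, windows covered in all 3 libraries of a time may be those detected most readily, so the ratios cannot tell a repeated gain from ease of detection. The stretch with the most such windows, singled out after its values were seen, held 19 of them on chromosome 19 from 36925501 to 36942500. A candidate explanation for the chromosome pattern is the density of H3K4me3 regions: across 23 chromosomes Spearman's rho was 0.86 and Pearson's r 0.92 (permutation p = 1e-05 each, the smallest it can give). Without chromosomes 17 and 19 Pearson's r was 0.82 (permutation p = 1e-05). Chromosome 22 held only 0.646 times its share, at a higher density than most. Copy number of this line could give such a pattern too and was not analysed here.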
